A study of Solanum lycopersicum with 6 samples.

How the data were processed

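Gene expression was measured by RNA sequencing in shoot apices of tomato (Solanum lycopersicum). Seedlings were grown for 14 to 18 days, fixed in acetone and dissected, and libraries were made with an Illumina TruSeq RNA kit, per the labels' protocols. The 6 libraries form 3 groups of 2: the wild-type (WT) apex, the apex of the leafless (lfs) mutant, and the pin-shaped shoot tip induced by spraying 1 mM TIBA (triiodobenzoic acid, an inhibitor of polar auxin transport). By the labels, the WT samples held the shoot apical meristem with the 2 youngest leaf primordia, whereas the lfs and TIBA samples held the meristem alone. The labels number the repeats but do not say whether they came from separate batches of plants, so the p-values measure the spread between these libraries, which may be partly technical.

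Reads were aligned with TopHat2 (2.0.10), counted per gene with HTSeq (0.6.1p1) and analysed with DESeq2 (1.6.3), per the submitters' processing notes. The genome build and annotation are not given in the sources used here. The deposited table held 34722 tomato gene identifiers with the authors' DESeq2-normalized counts, a signal made by dividing each library's gene counts by 1 size factor, per the file headers. It also held the authors' log2 fold changes, p-values and adjusted p-values for the 3 pairwise comparisons, per the file headers. The settings of that DESeq2 run are not given in the sources used here. All 208332 normalized values (100%) were whole multiples, within 0.001 reads, of what 1 read was worth in their library, so the read counts could be recovered exactly. Recovered reads totalled 17640302 to 26054787 per library. No sample column was left unused.

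The design fixed before the data were examined called for edgeR's quasi-likelihood test on raw counts with TMM normalization. Because the deposited values are normalized, the main test was instead limma (3.58.1, R 4.3.3) on log2(normalized count + 1), and edgeR (4.0.16) on the recovered reads became an alternative. The recovered reads would also have allowed the planned test, so the unit did not force this choice. The numbers of genes called by limma, limma with a replicate block, edgeR and the authors had been seen together before the analysis was written. The pseudocount of 1 and the minimum below were set with the deposited table at hand. A gene was tested when its normalized count reached 10 in at least 2 libraries, which left 19807 genes. The 3 groups were fitted together, since 2 libraries per group leave only 3 residual degrees of freedom, with an intensity trend and robust moderation. All calls use a Benjamini-Hochberg adjusted p under 0.05. Fold changes on the log2(value + 1) scale understate the change of genes with few reads. For a gene without a read in one group, the fold is a lower bound against 3 reads in each of that group's libraries. For a gene with 1 to 3 reads in one group, the ratio is given with an exact 95% interval. Such bounds and intervals cover counting error only, and a bound is not comparable with the lower limit of an interval.

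The pipeline was tested on simulated counts for the real genes with 200 genes changed in each comparison. For lfs against WT (19608 genes tested), 90.9% of the genes set to a 4-fold change and 43.9% of those set to a 2-fold change were recovered, and 6.99% of calls were false. For TIBA against WT (19599 genes) the shares were 90.9%, 44.4% and 4.96%. For lfs against TIBA (19598 genes) they were 89.9%, 52.0% and 6.00%. The simulation gave all 3 groups the same spread per gene, taken from a trend with abundance, so genes of like abundance shared 1 spread. It changed 200 genes per comparison, whereas the comparisons of the data called between 912 and 3681. In the data the median SD between replicates was 0.092 log2 units in WT, 0.16 in lfs and 0.23 in TIBA. These shares therefore need not hold for the real comparisons.

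Neither the table nor the reference gene table used here (RefSeq, assembly SLM_r2.1) pairs these identifiers with names: 0 of the 34722 identifiers matched. The 29 gene lists fixed by description could therefore not be filled, markers of other cell types among them, and genes are reported by identifier without names or functions. The rule for naming genes, fixed in advance, took the 6 largest changes in each direction among called genes with a mean of at least 5 CPM over the 6 libraries, both libraries of one group above both of the other, and a description. The description could not be required, and only the first 2 identifiers per direction are printed. The parts of the rule that drew on the lists, on descriptions and on the overlap name no gene here. Chromosomes are read from the identifiers, which carry them by convention. LFS alone is named: its identifier, Solyc05g013540, was written down before the data were examined, from memory of published work and not from the files, and could not be checked. A list of 19 identifiers, LFS included, had also been fixed in advance, from memory of published work, as regulators of tomato meristem, leaf and flower development. It could not be checked against any table, so all results for the listed regulators hold only as far as these identifiers are right. Nor is the list shown to be independent of published results on these samples. Its members are counted and not identified, apart from LFS and Solyc05g056620.1, which the naming rule also took. Of these, 17 were tested; the 16 other than LFS were analysed as a list, LFS having been taken out after its values were seen. List tests were camera with a preset correlation of 0.01 and with an estimated correlation, fry, and Fisher's exact test of the share called, each adjusted over the 3 comparisons.

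Replicates were compared before averaging. A chi-square test of read counts gave 9.79 per degree of freedom between the WT libraries, 31.7 between the lfs libraries and 42.0 between the TIBA libraries, so none is a second copy of another. Alternatives covered DESeq2 (1.42.0) and edgeR on recovered reads, other size factors, voom, other filters and pseudocounts (0.5 and 5), a stricter threshold, fits of only 2 groups, a weight per group, a replicate block and leaving out each library. The 2 comparisons that share the WT libraries were simulated 100 times, with all groups unchanged and 1 spread per gene for all of them.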

Results

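The series compared RNA from the shoot apex of the tomato lfs mutant, which forms no leaves, with that from the WT apex and from leafless pins induced by TIBA. Each of the 3 groups had 2 libraries. WT replicates held 23888387 and 25022897 gene-assigned reads, lfs replicates 19914834 and 26054787, and TIBA replicates 25774076 and 17640302. Between 22445 and 23125 genes had at least 1 read in a library, and the most abundant gene took between 0.529% and 1.03% of the reads. WT replicates were the closest to each other (Pearson r = 0.990 across genes on the log2 scale), followed by lfs (0.975) and TIBA replicates (0.962), while libraries of different groups correlated between 0.892 and 0.942. The median SD between replicates was 0.092 log2 units in WT, 0.16 in lfs and 0.23 in TIBA (n = 2 each). The first principal component (50.6% of the variance) placed both WT libraries apart from the 4 leafless ones, and the second (31.8%) placed lfs and TIBA libraries on opposite sides.

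**Figure D1:**
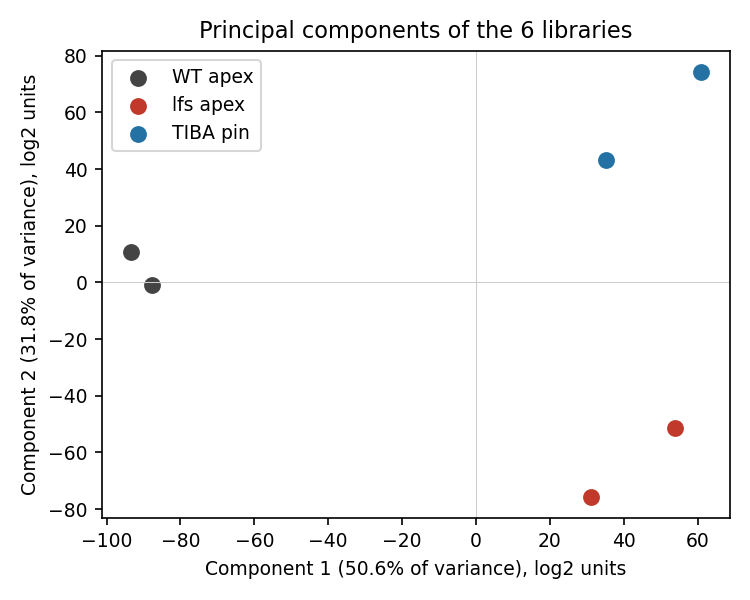
Principal components of log2(normalized count + 1) over 19807 genes, 1 point per library, coloured by group; axes are in log2 units. The WT libraries lie at -93.4 and -87.8 on component 1, the lfs and TIBA libraries between 31.1 and 61.0, and component 2 separates lfs (-51.5 and -75.6) from TIBA (43.1 and 74.3).

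The transcript of LFS, the AP2-type transcription factor gene affected in the mutant, was higher in the lfs apex than in either other group. LFS (Solyc05g013540.1, chromosome 5) stood at a normalized count of 708.5 ± 2.87 (SD, n = 2) in WT, 3459 ± 605 (SD, n = 2) in lfs and 459.6 ± 173 (SD, n = 2) in TIBA pins. These values rest on 787 and 820 reads in the WT libraries, 2992 and 4780 in the lfs libraries, and 703 and 282 in the TIBA libraries. The increase in lfs over WT was 4.84-fold (log2 2.27, SE 0.26, limma adjusted p = 0.0025), and lfs exceeded TIBA 7.73-fold (log2 2.95, SE 0.26, limma adjusted p = 0.0031). The TIBA pin differed from WT by a log2 value of -0.68 (SE 0.26), which did not pass the limma test (adjusted p = 0.11) except when TIBA replicate 1 was left out (log2 -1.07, adjusted p = 0.0091). A mutation need not lower the transcript that carries it, so the level does not by itself check the sample labels. The link between this identifier and LFS was given from memory of published work and could not be checked against the deposited table or the reference table.

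**Figure D2:**
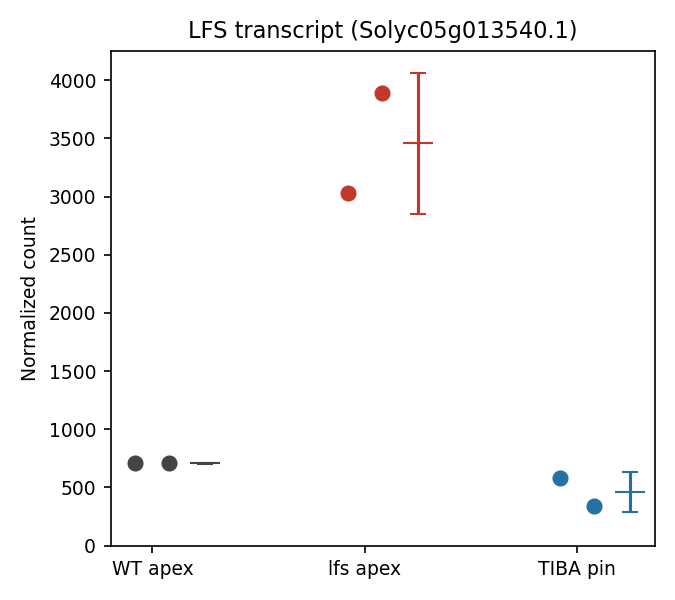
Normalized count of LFS per library, with 2 points per group and the group mean ± SD beside them; the axis starts at 0. Both lfs libraries (3031 and 3887) lie above the WT libraries (706.5 and 710.6) and the TIBA libraries (581.6 and 337.5).

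In the lfs apex 2810 of 19807 genes differed from WT, 1762 of them higher and 1048 lower (limma, adjusted p under 0.05). Among these, 1265 rose and 593 fell at least 2-fold. Solyc06g062370.2 (chromosome 6) showed the highest limma log2 increase that met the naming rule, 10.4 against 8.97 for Solyc05g056620.1. In edgeR with DESeq2 size factors the 2 values were 12.2 and 12.3. Solyc06g062370.2 rose from 0.433 ± 0.613 (SD, n = 2) in WT, a single read, to 2597 ± 2650 (SD, n = 2) in lfs, a ratio of 6360 (exact 95% interval 1140 to 251000). Its 2 lfs libraries differed widely, it stood at 236.6 in TIBA pins, and voom did not call it (adjusted p = 0.081, against 6.8e-10 to 0.0085 in the other alternatives). Solyc05g056620.1 (chromosome 5) had no read in WT and 563.6 ± 363 (SD, n = 2) in lfs, at least 213-fold higher, with a mean of 77.8 in TIBA pins; it is also 1 of the 16 listed regulators counted for this comparison. Solyc10g074440.1 (chromosome 10) was at 1037 ± 88.2 (SD, n = 2) in WT and at a single read over both lfs libraries, a ratio of 2300 (exact 95% interval 413 to 91000). Solyc03g114560.2 (chromosome 3) was at 835.4 ± 230 (SD, n = 2) in WT and likewise at a single read in lfs, a ratio of 1850 (exact 95% interval 331 to 72900). The last 2 genes had TIBA means of 768.7 and 3189. All 4 had limma adjusted p-values between 8.9e-05 and 0.00063. The ratio for Solyc06g062370.2 was 3230 without WT replicate 1, 10100 without lfs replicate 1 and 1630 without lfs replicate 2, and became at least 964-fold without WT replicate 2, which held the read. The bound for Solyc05g056620.1 was at least 116-fold without lfs replicate 2. The ratio for Solyc10g074440.1 was 1030 without lfs replicate 2 and at least 425-fold without lfs replicate 1, and that for Solyc03g114560.2 was 1020 without lfs replicate 1 and at least 275-fold without lfs replicate 2.

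Of the 16 listed regulators of meristem, leaf and flower development other than LFS, 2 rose and 5 fell in lfs against WT, and 9 did not pass the test over all genes (limma). Adjusted over the list alone, 4 rose and 6 fell. Their log2 changes ran from -4.68 to 8.97 with a median of -0.34. The list held a larger share of called genes (43.8%) than all tested genes (14.2%). Fisher's exact test, two-sided, gave adjusted p = 0.0052, although genes are not independent replicates and the comparison was not matched on expression. Only the WT samples held leaf primordia, so tissue makeup alone could raise the share called among regulators of leaf development. As a set the list was not called as moving one way relative to other genes (camera adjusted p = 0.21, and adjusted p = 0.62 with an estimated correlation). Change in either direction was called (fry, mixed adjusted p = 5.1e-06). The fry test asks whether members changed at all and makes no comparison with other genes, of which 14.2% were called. It therefore does not set the list apart. The number of listed regulators called was 1 without WT replicate 1 and 2 without WT replicate 2 (limma).

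The number of genes called in lfs against WT moved with each library left out; the 3 groups share 1 estimate of the spread, and the lone library of a group is assumed to vary like the others. It was 562 without WT replicate 1, 886 without WT replicate 2, 1030 without lfs replicate 1, 1568 without lfs replicate 2, 4410 without TIBA replicate 1 and 4428 without TIBA replicate 2. The 1858 genes with at least a 2-fold change became 562 without WT replicate 1 (405 higher and 157 lower), 881 without WT replicate 2 and 966 without lfs replicate 1, 1085 with a mean of at least 5 CPM required, and 903 at an adjusted p under 0.01 (limma). No called gene that was still tested changed sign without a WT or lfs library. A gene whose sign hung on 1 library would be too spread between replicates to be called, so this adds no support. Leaving out a TIBA library does not alter the estimated change.

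In the TIBA pin 3681 genes differed from WT, 2142 higher and 1539 lower (limma, adjusted p under 0.05). At least 2-fold changes numbered 1440 upwards and 809 downwards. Solyc06g060640.1 (chromosome 6) had no read in WT and a normalized count of 1020 ± 86.6 (SD, n = 2) in TIBA pins, at least 385-fold higher, with a mean of 43.7 in lfs. Solyc04g082910.1 (chromosome 4) also had no read in WT and stood at 619.5 ± 104 (SD, n = 2) in TIBA pins, at least 234-fold higher, with a mean of 446.2 in lfs. Solyc08g079100.2 (chromosome 8) fell from 3674 ± 93.1 (SD, n = 2) in WT to 12.4 ± 2.33 (SD, n = 2) in TIBA pins (log2 -8.11, SE 0.48) and was at 6.40 in lfs. Solyc03g111820.2 (chromosome 3) fell from 2064 ± 323 (SD, n = 2) to 36.5 ± 39.7 (SD, n = 2) (log2 -6.37, SE 0.95) and was at 3.44 in lfs. Their limma adjusted p-values lay between 5.3e-05 and 0.0067; that of Solyc03g111820.2 was 0.055 without WT replicate 1 and 0.00011 to 0.012 in the alternatives that left out no library. The log2 change of Solyc03g111820.2 was -7.77 without TIBA replicate 1 and -4.97 without TIBA replicate 2.

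Of the 16 listed regulators, 3 rose, 6 fell and 7 did not pass the test in TIBA against WT (limma), and the counts were identical when adjusted over the list alone. Their log2 changes ran from -5.40 to 6.23 with a median of -0.27. The share called was 56.2%, against 18.6% of all tested genes (Fisher's exact test, two-sided, adjusted p = 0.0025). The limits of this comparison given for lfs against WT hold here too. The set was not called as moving one way (camera adjusted p = 0.18, and adjusted p = 0.62 with an estimated correlation). Change in either direction was called (fry, mixed adjusted p = 9.4e-05), again without comparison with other genes. The number called was 4 without WT replicate 1 and 5 without WT replicate 2 (limma).

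The number called in TIBA against WT was 661 without WT replicate 1, 717 without WT replicate 2 and 6555 without TIBA replicate 1. In the last case the excess of increases was no longer present. There the lone TIBA library was assumed to vary like the WT and lfs libraries. Their median SDs between replicates were smaller (0.092 and 0.16, against 0.23 in TIBA), so the number called in that fit is probably too high. The 2249 genes with at least a 2-fold change became 661 without WT replicate 1 (521 higher and 140 lower), 716 without WT replicate 2 and 3593 without TIBA replicate 1 (1863 higher and 1730 lower), 1412 with a mean of at least 5 CPM required, and 965 at an adjusted p under 0.01 (limma). In the authors' deposited table, 2997 genes passed an adjusted p of 0.05 for lfs against WT and 3686 for TIBA against WT. The authors' deposited table shared 2484 and 3224 of these calls, in the same direction, with the limma calls, and 0 were opposite. Both rest on the same libraries, so opposite calls could hardly arise. The authors' adjusted p-values covered 25845 genes, against 19807 tested here and 25425 with any read in these libraries, so the gene sets differ.

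Many genes were called against WT in both the lfs apex and the TIBA pin. In both, 1057 genes were higher and 520 lower than in WT, which is 56.1% of the lfs calls and 42.8% of the TIBA calls. Independent lists of these sizes would share 190.5 and 81.4 genes, which leaves the shared WT libraries out of account. Among the shared genes the median absolute change was 1.61 log2 units in both lfs and TIBA, and the change was larger in TIBA for 48.7% of them. Of the 16 listed regulators, 4 were lower and 2 higher in both, 2 were called lower and 1 higher only in TIBA, 1 was called lower only in lfs, and 6 were called in neither. A call in one group only is no test of the difference between them. Of the genes named for the comparisons with WT, Solyc06g062370.2, Solyc05g056620.1, Solyc06g060640.1 and Solyc04g082910.1 were called higher in both, and Solyc08g079100.2 and Solyc03g111820.2 lower in both (limma). Solyc03g114560.2 was lower in lfs and higher in TIBA pins (log2 1.96, SE 0.345, limma adjusted p = 0.0111), and Solyc10g074440.1 was lower in lfs and not called in TIBA pins (log2 -0.52, SE 0.458, limma adjusted p = 0.452).

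Fold changes against WT correlated across the 19807 genes (Pearson r = 0.658, Spearman rho = 0.647); genes are not independent replicates. Both comparisons use the same WT libraries. All groups simulated as unchanged, with 1 spread per gene, gave r = 0.499 (range 0.471 to 0.519) and 0 shared calls. With nothing set to change, 0 shared calls had to follow, so this gives no chance value for the overlap. The covariance was 0.737, against 0.0628 in the simulations, a difference of 0.674. Equal spreads fix the simulated r near 0.499, while the real WT replicates were the closest to each other. The simulated r and covariance are therefore only rough baselines. The simulations already include the shared WT libraries, at a spread common to all groups. The median SD between replicates was 0.092 in WT, against 0.16 in lfs and 0.23 in TIBA. For a typical gene the simulations therefore probably overstate what the spread of the shared WT libraries adds. The WT group is too small to be split with 2 libraries on each side, so a shift common to both WT libraries could not be told from the excess. Both leafless groups were dissected without primordia and WT with them, so tissue makeup differs in the same way in both comparisons. The shared count was 264 without WT replicate 1, 406 without WT replicate 2, 658 without lfs replicate 1 and 2566 without TIBA replicate 1.

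**Figure D3:**
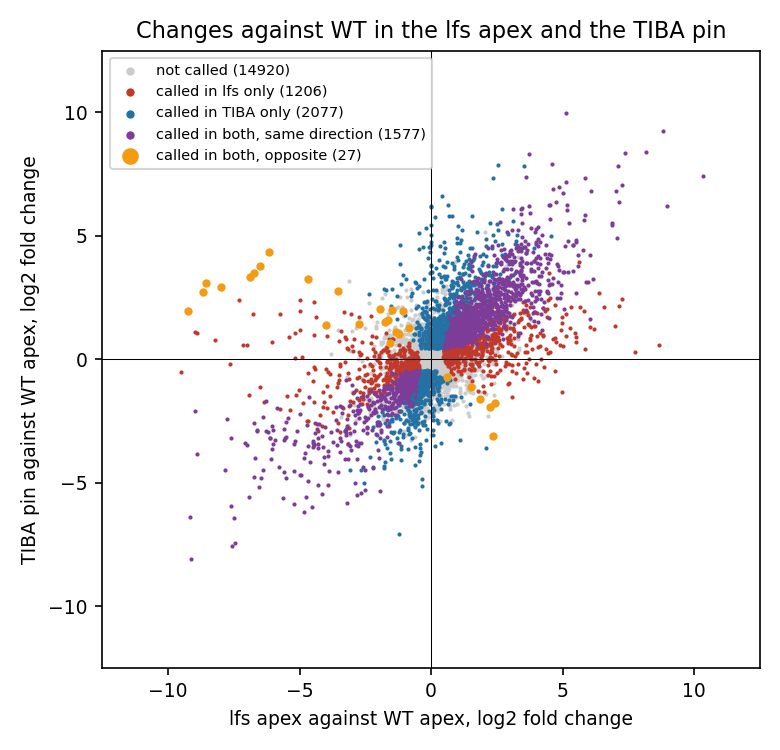
Log2 fold change against WT in the lfs apex (x axis) and the TIBA pin (y axis), 1 point per gene for 19807 genes, coloured by the limma calls at an adjusted p under 0.05. The 1577 genes called in both with the same direction lie along the diagonal, and 27 genes called in opposite directions lie in the other 2 quadrants.

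The direct comparison of the 2 kinds of leafless apex found 912 genes, 390 higher in lfs and 522 higher in TIBA pins (limma, adjusted p under 0.05). Solyc09g072750.2 (chromosome 9) stood at 8271 ± 4150 (SD, n = 2) in TIBA pins and at 1.42 ± 0.858 (SD, n = 2) in lfs, 3 reads in all, a ratio of 5720 (exact 95% interval 1960 to 27700), with a mean of 896.2 in WT. Solyc09g092760.2 (chromosome 9) was at 4380 ± 2910 (SD, n = 2) in TIBA pins and at a single read in lfs, a ratio of 8880 (exact 95% interval 1590 to 351000), with a mean of 589.8 in WT. In the other direction, Solyc02g071730.2 (chromosome 2) was at 640.7 ± 703 (SD, n = 2) in lfs and a single read in TIBA pins, a ratio of 1420 (exact 95% interval 255 to 56200), and had no read in WT. Solyc02g063480.2 (chromosome 2) was at 394.7 ± 227 (SD, n = 2) in lfs and at 2 reads in TIBA pins, a ratio of 421 (exact 95% interval 116 to 3480), with a mean of 0.867 in WT. Limma adjusted p-values of these 4 genes lay between 4.8e-05 and 0.0085; without lfs replicate 2 those of Solyc02g071730.2 and Solyc02g063480.2 were 0.058 and 0.056. Solyc02g071730.2 was also not called by voom (adjusted p = 0.17) or with a mean of at least 5 CPM required (limma adjusted p = 0.052), and its lowest adjusted p in any alternative was 0.0040. The ratio for Solyc02g071730.2 was 2330 without lfs replicate 1, 294 without lfs replicate 2 and 581 without TIBA replicate 1, and at least 258-fold without TIBA replicate 2. That for Solyc02g063480.2 was 239 without lfs replicate 2, and that for Solyc09g072750.2 was 9510 without lfs replicate 1 and 3820 without lfs replicate 2. For Solyc09g092760.2 it was 3950 without lfs replicate 2, 14300 without TIBA replicate 1 and 5150 without TIBA replicate 2, and at least 1800-fold without lfs replicate 1.

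Of the 1206 genes called against WT in lfs but not in TIBA pins, 313 also differed between lfs and TIBA, as did 336 of the 2077 called in TIBA pins but not in lfs. Of the 1577 shared genes, 123 differed between the 2 leafless groups. These counts are parts of the 912 calls, which became 369 with only the 4 lfs and TIBA libraries and 360 with a weight per group. The counts were not made anew in those fits and may be too high. Of the 16 listed regulators, 3 were higher and 1 lower in lfs than in TIBA pins and 12 did not pass the test; adjusted over the list alone 5 were higher and 1 lower. Their log2 differences ran from -1.90 to 2.74 with a median of 0.14. Of the list 25% were called, against 4.60% of all tested genes (Fisher's exact test, two-sided, adjusted p = 0.0052), again without matching on expression. The set was not called as moving one way (camera adjusted p = 0.18, and adjusted p = 0.62 with an estimated correlation). Change in either direction was called (fry, mixed adjusted p = 0.0079), again without comparison with other genes. The number called was 0 without either WT replicate (limma; with all libraries 6 had an unadjusted p under 0.05 and edgeR called 4), 2 without lfs replicate 1, and 1 without lfs replicate 2 or TIBA replicate 2. The camera p, 0.10 before adjustment, was 0.018 without lfs replicate 1 and 0.034 without TIBA replicate 1.

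In place of 912, a fit of the 4 lfs and TIBA libraries alone called 369 genes and none of the 16 regulators at an adjusted p under 0.05 (limma; 6 of the 16 at an unadjusted p under 0.05, and 4 called by edgeR on all libraries). The count was 373 without WT replicate 1, 368 without WT replicate 2, 438 without lfs replicate 1, 105 without lfs replicate 2 and 2777 without TIBA replicate 1, where more genes were higher in lfs (1641) than in TIBA pins (1136). Without TIBA replicate 1 the lone TIBA library was again assumed to vary like the other groups, so that count is probably too high. For lfs against TIBA the authors' deposited table gave an adjusted p under 0.05 to 1460 genes, 606 higher in lfs and 854 higher in TIBA. The authors' deposited table and limma called 815 genes in common, in the same direction.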

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

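The LFS comparisons and the fits with a library left out were planned, and their use to weigh explanations was chosen after the results were seen.

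The LFS transcript moved apart in the 2 leafless groups: its change against WT in the lfs apex exceeded that in the TIBA pin by 2.95 log2 units (SE 0.26, limma adjusted p = 0.0031), with both lfs libraries above and both TIBA libraries below the WT libraries. If the absence of leaf primordia from the dissected tissue were alone the cause, and TIBA did not act on this gene, the TIBA pin would show a similar increase. Its log2 change was -0.676 (95% interval -1.28 to -0.0737), against 1.67 to 2.88 in lfs, which argues against that explanation. A single lfs library as the cause is argued against too, since the highest limma adjusted p against WT with either of them left out was 0.027. A lowering of LFS by TIBA that masks a tissue effect, and an effect of the lfs mutation on its own transcript, stay open and were not tested.

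A total of 27 genes were called in opposite directions against WT, 6 higher in lfs and lower in TIBA pins and 21 lower in lfs and higher in TIBA pins. These genes were selected for opposite calls against the same WT libraries, so the direct limma test of lfs against TIBA, which all 27 passed, adds no support.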

How the results depend on the processing

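The replicate-left-out fits and most alternatives were fixed before the data were examined. The test of the fixed design, edgeR with TMM and without the block, was run on the recovered reads after the data were seen. It called 2777 genes for lfs against WT, 3467 for TIBA against WT and 847 for lfs against TIBA. Added after the data were seen were edgeR with TMM and the block, voom, the pseudocounts and the group weights. The weights came after the counts with 1 library left out. Where an alternative estimates the change anew (DESeq2, edgeR, voom and the pseudocounts), no gene called by limma and still tested there changed sign. Leaving out a library of the groups compared gave no reversal either. Genes whose sign hung on 1 library would be too spread to be called, so that result was fixed in advance. The other alternatives leave the estimated change as it is and could show no reversal. For lfs against WT the count of 2810 became 4494 with only those 4 libraries, 5020 with a weight per group and 972 at an adjusted p under 0.01, and ranged from 562 to 4428 with 1 library left out; the other alternatives gave 1936 (edgeR with TMM and the block) to 3699 (DESeq2). For TIBA against WT, 3681 became 1062 at 0.01 and ranged from 661 to 6555 with 1 library left out. For lfs against TIBA, 912 became 1993 with DESeq2, 565 with a mean of at least 5 CPM, 369 with only those 4 libraries, 360 with group weights and 176 at 0.01, with 105 to 2777 when 1 library was left out; edgeR with TMM gave 847. The group weights were 2.5 for WT, 0.882 for lfs and 0.453 for TIBA, so the spread differed between groups. The shared calls (1577) became 458 at 0.01 and 1045 with an added 2-fold limit, and 264 to 2566 with 1 library left out. The correlation of fold changes (0.658) was 0.591 with DESeq2 and 0.568 to 0.696 with 1 library left out. LFS stayed called in lfs against WT (log2 2.10 to 2.45) and against TIBA (2.56 to 3.34, the highest limma adjusted p rounding to 0.05, without lfs replicate 2, and the lowest being 0.0015 with 1 library left out), and its TIBA change ran from -1.07 to -0.284. The listed regulators called numbered 7 for lfs against WT (4 at 0.01, 1 to 9 with 1 library left out), 9 for TIBA against WT (4 to 10) and 4 for lfs against TIBA, where it was 0 at 0.01 (limma; 6 at an unadjusted p under 0.05, 4 by edgeR) and 0 with only those 4 libraries, 1 with voom and with group weights, and 0 to 6 with 1 library left out. The camera p for that list in lfs against TIBA ran from 0.018 to 0.63 with 1 library left out, from 0.067 to 0.61 in lfs against WT and from 0.076 to 0.17 in TIBA against WT. A weight per group and the fits of only 2 groups leave the estimated changes as they are. Their shifts (2810 to 5020 and 4494 for lfs against WT, 912 to 360 and 369 for lfs against TIBA) therefore come from the estimate of the spread. Beyond this, the threshold, the filter and the number of libraries, the cause of the shifts was not tested. The deposited values already carry DESeq2 size factors, so that alternative was not run for the list tests.

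The repeat numbers are not stated to pair the libraries, and deviations of same-numbered libraries from their group means correlated at 0.015 (WT with lfs), -0.051 (WT with TIBA) and -0.14 (lfs with TIBA). With a replicate block the calls were 2092 for lfs against WT, 2743 for TIBA against WT and 474 for lfs against TIBA, or 466 in edgeR, and 2 of the listed regulators were called in lfs against TIBA under either block. At these depths a gene without a read in a library is not shown to be without expression, since a count of 0 allows up to 3 reads.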

Other observations

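Some genes were on in 1 group and without a read in another. No read was found in either WT library for 10 genes that reached a normalized count of 10 in all 4 leafless libraries, and 3 genes present in both WT libraries had no read in any leafless library. Against WT alone, 51 genes present in both WT libraries had no read in lfs and 9 had none in TIBA pins, while 37 genes without a read in WT were present in lfs and 41 in TIBA pins. A count of 0 allows up to 3 reads in each library, so these genes are not shown to be without expression.

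The tests on genes without a read in lfs were chosen after such genes had been counted in each group and pair of groups. Neighbouring pairs were first counted for the called genes of every comparison and direction, with chromosome shares and windows of genes looked at too and not pursued; the test at distance 5 was then set before its result was seen, and that of flanking pairs after the distances were seen but before its own result.

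A set of 18 genes had no read in either lfs library although they reached a normalized count of 10 in all WT and TIBA libraries, and the mirrored pattern, without a read in TIBA pins, held 0 genes. Fewer reads in lfs are argued against as the cause, since the lfs libraries together held 45969621 reads, 106% of the 43414378 in the TIBA libraries. The genes lie on 8 chromosomes, which argues against 1 deleted segment in the mutant line. A candidate explanation is a shared source of RNA, such as a tissue or a physiological state, lacking in the lfs apex. The genes moved together between the TIBA libraries, 16 of 18 being higher in replicate 2 with a median log2 ratio of 0.771. That was at percentile 99.98 of 10000 lists matched on expression, although between the WT libraries the median ratio was -0.148 (percentile 6.45). The lists drew genes independently, so any genes expressed together could reach such a percentile. The test therefore cannot tell a shared source of RNA from genes regulated together. An effect of the lfs genotype on each gene stays open, and the source cannot be named without gene annotation.

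Among the tested genes, those higher in both leafless groups than in WT lay next to each other in identifier order more often than shuffled calls: 132 neighbouring pairs among 1056 genes on the 12 numbered chromosomes, against 56.7 expected (permutation p = 1e-04, the smallest that 10000 shuffles can give, one-sided). Order and distance count tested genes only, so neighbours here can have untested genes between them. Genes lower in both showed 40 pairs against 13.7 (permutation p = 1e-04, likewise the smallest possible), but 20, 18 and 13 pairs at distances 2, 5 and 20, each inside the 95% range of 7 to 21 (permutation p = 0.058, 0.14 and 0.60). For higher genes there were 85 pairs at distance 2 (permutation p = 2e-04), 70 at distance 5, inside the range of 43 to 71 although the one-sided permutation p was 0.036, and 64 at distance 20, inside the range of 42 to 70 (permutation p = 0.15). Pairs of higher genes that flank a gene not called numbered 61, inside the range of 40 to 68 (permutation p = 0.16). Reads shared between overlapping or adjacent genes may contribute to the pairs of direct neighbours, while clustering over a few genes stays open for the higher genes, and tandem copies regulated together were not tested.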
